A study of Mus musculus with 16 samples.

How the data were processed

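RNA was measured on expression arrays from regulatory T cells (Treg) sorted from the pooled lymph nodes of adult female C57BL/6 mice. Per the labels the cells were split by surface CD103 (encoded by Itgae) and ICOS into 4 subsets, called here double-negative, CD103 single-positive, ICOS single-positive and double-positive. RNA was taken directly after sorting (fresh) or after 3 days in a CD4 T cell suppression assay (activated). In that assay 200000 Treg of a subset were cultured with 1000000 congenic naive CD4 cells, 2000000 irradiated splenocytes lacking Rag2 and 0.5 ug/ml soluble anti-CD3. The Treg were then re-sorted as CD4-positive, CD25-positive cells lacking the congenic marker of the naive cells. Each of the 16 arrays received label made from 270 ng of total RNA, and each of the 8 groups had 2 arrays, labelled biological replicates 1 and 2.

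The deposited values are log2 intensities, with 1 value for each of 35556 probe sets on each array. The submitters' processing notes name RMA and the affy package, and the versions and settings are not given in the sources used here. RMA run with its defaults corrects background, applies quantile normalization to the probes and summarises them per probe set, and whether the defaults were used is not stated. The deposited values lie between 3.02 and 14.2 on every array, and the array medians between 6.26 and 6.48. No second normalization was applied. Quantile normalization applied again would have changed no value by more than 0.221. Arrays carry no counting depth, and the number of arrays per group limits the precision. Intensities include background, so a fold against a group whose level lies below the array medians can understate the difference.

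The annotation pairs 21789 probe sets with exactly 1 gene symbol, 1621 with several and 12146 with none. Probe sets with 1 symbol were used, and for the 999 genes with several of them the probe set with the highest mean over all arrays stood for the gene, which left 19938 genes. No dim genes were removed. Gene names were checked by gene identifier against the RefSeq annotation of GRCm38.p6 for 21698 probe sets, and 0 symbols changed. Positions are not given, because the build behind the array annotation is not stated.

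The main test was limma 3.58.1 in R 4.3.3, fitted once to all 16 arrays with 8 group means, which leaves 8 residual degrees of freedom and a prior of 2.90. The 8 groups share 1 estimate of the spread per gene, so an array that departs from its partner widens the error of that gene in every comparison. There were 12 comparisons. In each state these were the CD103 difference averaged over ICOS, the ICOS difference averaged over CD103, the interaction of both, and double-positive against double-negative, and in fresh cells also CD103 single-positive against ICOS single-positive. Activated cells were compared with fresh cells over the 4 subsets, and the CD103 and ICOS differences were compared between the states. A gene passed at a Benjamini-Hochberg adjusted p below 0.05 over the 19938 genes of a comparison. The p-values of single genes measure the spread between 2 biological replicates per group, pooled over the 8 groups. The comparisons, the lists and the rules for naming genes were fixed before the data were examined.

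The genes named are the largest differences that passed, up to 10 in each direction (5 where a difference between differences was tested). They also had to have the same sign in the replicate 1 arrays alone and in the replicate 2 arrays alone. Predicted genes, small RNA, histone and antigen receptor genes were left out. Up to 4 passing members of each fixed list are named as well. Itgae, Icos, Foxp3 and Il2ra were read as checks of the labels only.

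Gene lists were fixed for 20 groups. They cover Treg core genes, effector Treg genes, naive and central T cell genes, homing and adhesion, helper lineages, follicular T cells, cell cycle, T cell receptor immediate early genes, costimulation and coinhibition, and suppression and cytolysis. They also cover the TGF-beta pathway, glycolysis, cholesterol synthesis, interferon response, heat shock and stress, and markers of B cells, myeloid and dendritic cells, CD8 T and NK cells, activated conventional CD4 T cells, and erythroid cells and platelets. Of 306 listed genes 276 were measured, and 30 have no probe set named with their symbol alone. Lists were tested with camera in limma, with its preset correlation of 0.01, which asks whether a list's genes move more than other genes. Its p-values rest on the spread across genes at the correlation used, and do not measure the spread between replicate arrays. The adjustment ran over the 240 tests of 20 lists in 12 comparisons. Of 113 calls, 3 hold with an estimated correlation. These are the cell cycle list for ICOS in fresh cells and for the fresh single-positive subsets, and the follicular list for the interaction in fresh cells. Counts adjusted over the list alone are given beside counts over all genes.

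The labels state that the series came from independent experiments, but not which experiment a replicate number stands for, so the number was left out of the model. Alternatives were a replicate block, only the arrays of the state compared, a dim-gene filter that keeps 11635 genes, other scalings (quantile, median centring, cyclic loess), an intensity trend, robust variance, array weights, the mean over a gene's probe sets, all probe sets, a minimum absolute log2 difference of 1, and each array left out in turn. Lists were also tested with an estimated correlation, with fry, with a block and with the filter. After the array labelled activated ICOS single-positive replicate 2 was seen to stand apart, the block, the filter and the list tests were also run without it.

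Simulations had 50 changed genes at each of 4 sizes, for ICOS in fresh cells. Limma recovered 22 of 50 at a log2 difference of 0.5, 41 at 1, 48 at 2 and 50 at 3, with 8 false calls among 169. The rates may not hold where groups share replicate differences, as here. Plots used Python 3.11.15 and matplotlib 3.10.9. Every value column was used.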

Results

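The series measured gene expression in 4 subsets of lymph node Treg, which differ in surface CD103, an integrin chain that binds E-cadherin, and in ICOS, a costimulatory receptor. Each subset was measured fresh and after a 3 day suppression assay, with n = 2 arrays per group and 16 arrays in all. The labels set the question by the design: how the subsets differ before activation, how they differ after it, and how activation changes them.

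The sort genes followed the labels on the fresh arrays. The mean log2 level of Itgae was 7.53 ± 0.39 (SD, n = 2) in double-negative and 8.96 ± 0.33 in ICOS single-positive cells, and 11.83 ± 0.08 in CD103 single-positive and 12.35 ± 0.03 in double-positive cells. That of Icos was 10.49 ± 0.14 and 11.34 ± 0.18 in the ICOS-negative subsets and 12.63 ± 0.03 and 13.23 ± 0.11 in the ICOS-positive ones. The activated arrays followed them less closely, and the subset names below are those of the labels. Itgae on ICOS single-positive replicate 1 lay above both CD103 single-positive arrays (9.94 and 9.87), and Icos was 11.25 on ICOS single-positive replicate 2, against 11.63 to 12.12 on the ICOS-negative arrays. Foxp3, the lineage transcription factor of Treg, lay between 11.69 and 12.84 on 15 arrays. On the array labelled activated CD103-negative ICOS-positive replicate 2 it was 8.53, against 12.64 on its partner, 17.3-fold lower. All 20 Treg core genes were lower on that array than on its partner (median log2 difference -1.85), and 14 of 16 naive and central T cell genes were higher (median 0.47). The medians of both arrays differed by 0.017, and 685 genes differed more than 2-fold between them, against at most 413 in any other pair. Counts without this array are given beside each comparison.

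**Figure D1:**
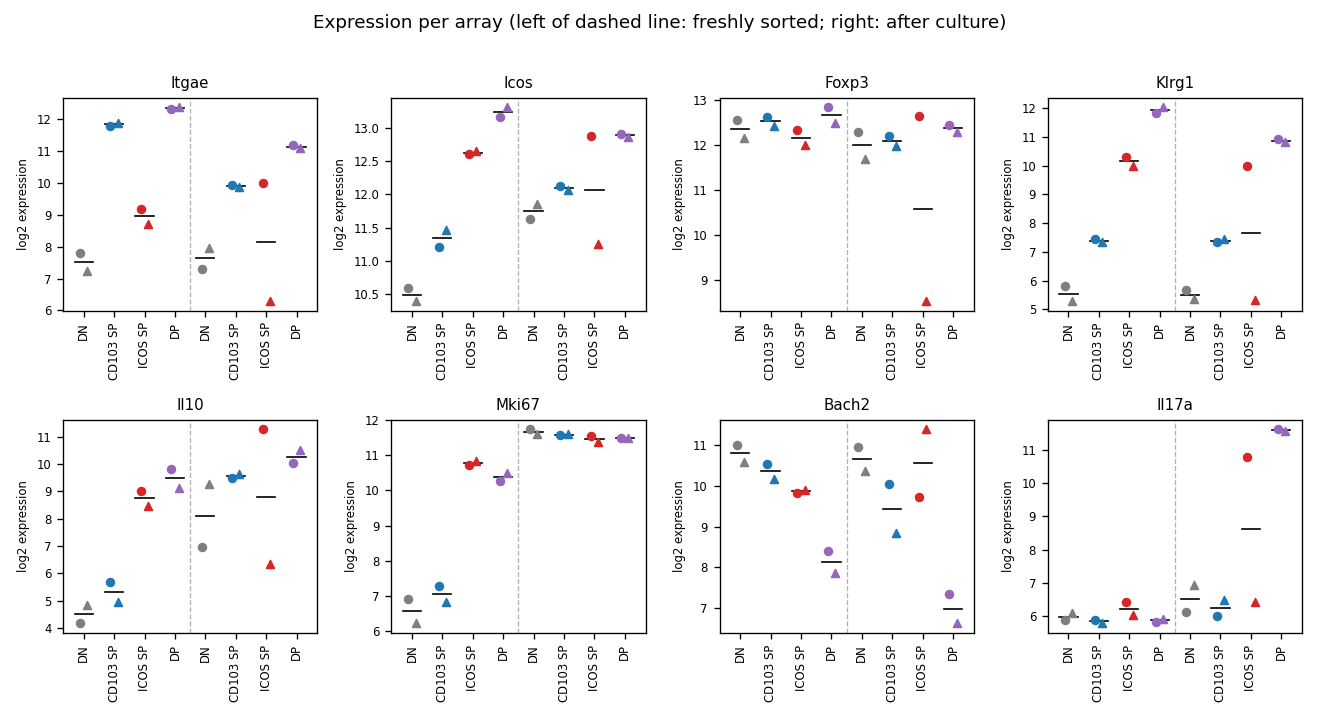
Log2 intensity (vertical axis) of Itgae, Icos, Foxp3, Klrg1, Il10, Mki67, Bach2 and Il17a in the 4 subsets, fresh to the left of the dashed line and activated to the right. Circles are replicate 1 arrays, triangles replicate 2 arrays and black lines group means (n = 2). Foxp3 is 8.53 on an activated ICOS single-positive array and at least 11.69 on the other 15.

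Of the comparisons among fresh cells, that by ICOS held the most genes. Klrg1, an inhibitory receptor of differentiated T and NK cells, was 23.7-fold higher in the ICOS-positive subsets (probe set 10547590, log2 difference 4.57, SE 0.72, adjusted p = 0.00308). Its mean log2 level was 5.55 ± 0.35 (SD, n = 2) in double-negative, 7.39 ± 0.08 in CD103 single-positive, 10.14 ± 0.21 in ICOS single-positive and 11.93 ± 0.14 in double-positive cells. Il10, a suppressive cytokine, was higher (probe set 10349603, log2 difference 4.19, SE 0.85, adjusted p = 0.0134), with 8.46 to 9.82 on the ICOS-positive arrays and 4.19 to 5.68 on the ICOS-negative ones. The proliferation marker Mki67 was 13.8-fold higher (probe set 10568714, log2 difference 3.78, SE 0.15, adjusted p = 2.14e-07).

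The other strong rises in fresh ICOS-positive cells were Ccr2, a chemokine receptor (log2 difference 4.09), S100a6 (3.82), the cyclin Ccna2 (3.78), the granule protease Gzmb (3.61), the inhibitory receptor Havcr2 (3.56), Prdm1, which encodes the transcriptional repressor Blimp-1 (3.45), and Gcnt1, a glycosyltransferase (3.35). Gzmb differed by 2.57 in the replicate 1 arrays and by 4.65 in the replicate 2 arrays. The strongest falls were Arhgap20 (log2 difference -3.32), Treml2 (-2.68), Gsta4 (-2.28), Gata1 (-2.20), Khdc1a (-2.19), St8sia6 (-2.16), the survival gene Bcl2 (-2.08), Atp1b1 (-1.91), Gpr83 (-1.91) and Stra6 (-1.91). In all 817 genes were higher and 484 lower in ICOS-positive cells, and 979 and 579 without the array that stands apart. With 1 fresh array left out the total fell to as few as 771, without ICOS single-positive replicate 2.

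All 26 measured cell cycle genes rose with ICOS in fresh cells, and all 26 adjusted over the list alone (median log2 difference 1.61, list test adjusted p = 6.66e-56, adjusted p = 0.0401 with an estimated correlation). Kif11 rose by 3.34 and Ccnb2 by 3.25. Of 22 effector Treg genes 17 rose and 0 fell, with 20 rising adjusted over the list alone (median 1.69, adjusted p = 1.53e-23, adjusted p = 0.14 with an estimated correlation). Of 25 homing and adhesion genes 12 rose and 1 fell, or 17 and 1 adjusted over the list alone (adjusted p = 1.57e-13, adjusted p = 0.188 with an estimated correlation). The chemokine receptors Cxcr6 and Ccr3 rose by 3.27 and 2.65. Of 16 naive and central T cell genes 9 fell, or 13 adjusted over the list alone (median -0.95, adjusted p = 4.89e-08, adjusted p = 0.198 with an estimated correlation). Among them were Bach2, a repressor of effector genes (log2 difference -1.59), Id3 (-1.30) and Actn1 (-1.25). With an estimated correlation and without the array that stands apart, adjusted p = 0.0157 for effector Treg, homing and suppression genes and 0.0252 for the cell cycle.

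Smaller groups also moved with ICOS in fresh cells, but lists share genes: Lag3, Pdcd1 and Fgl2 are effector genes too. Of 18 suppression and cytolysis genes 7 rose, or 8 adjusted over the list alone, among them Fgl2 (2.35) and Lgals3 (2.10). Their adjusted p = 9.99e-08, or 0.14 with an estimated correlation. Of 17 costimulation and coinhibition genes 5 rose, or 7 adjusted over the list alone, among them Tigit (2.52), Lag3 (1.64) and Pdcd1 (0.92). Their adjusted p = 8.76e-06, or 0.231 with an estimated correlation. Of 13 glycolysis genes 5 rose, or 8 adjusted over the list alone, among them Pgam1 (0.92), Tpi1 (0.80), Pgk1 (0.61) and Pkm (0.61). Their adjusted p = 8.21e-06, or 0.304 with an estimated correlation. Of 13 helper lineage genes 3 rose, or 5 adjusted over the list alone: Il23r (3.34), Il21 (2.34, with 4.40 in CD103-negative and 0.28 in CD103-positive cells, passing in 4 of 16 fits with 1 array left out) and Ahr (1.999), with adjusted p = 3.51e-05 and adjusted p = 0.207 with an estimated correlation. Of 13 follicular genes 4 rose, and 4 adjusted over the list alone, among them the decoy receptor Il1r2 (2.95) and Tox2 (1.43). Their adjusted p = 0.00171, or 0.14 with an estimated correlation. Of 9 genes of activated conventional CD4 T cells 2 rose, or 3 adjusted over the list alone, Il21 and Cd40lg (0.70), with all 9 positive (median 0.295), adjusted p = 6.22e-04 and adjusted p = 0.287 with an estimated correlation. Of 16 cholesterol synthesis genes 1 rose, Stard4 (0.61), with adjusted p = 0.0449, or 0.566 with an estimated correlation. The Treg core list was not called (3 rose, 1 fell of 20, and the same adjusted over the list alone, adjusted p = 0.197), with Tigit, Capg (0.95) and Tnfrsf4 (0.56) higher and Gpr83 lower. Of the T cell receptor immediate early genes 1 of 18 fell, Myc (-0.77), and the list was not called (adjusted p = 0.608).

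CD103 marked fewer genes in fresh cells. Ptgdr2, a prostaglandin D receptor, was 2.53-fold higher in the CD103-positive subsets (probe set 10461583, log2 difference 1.34, SE 0.16, adjusted p = 0.0128), and Hpgds, a prostaglandin D synthase, was 2.19-fold higher (probe set 10545101, log2 difference 1.13, SE 0.09, adjusted p = 0.00158). Also higher were the kinase Blk (log2 difference 1.31), Cd101 (1.24), Abi3bp (1.14), Lyz1 (1.14), Hoxb4 (1.11), the NADPH oxidase subunit Cybb (1.09), Cd8a (1.003) and Susd4 (0.97). These are averages over ICOS: Abi3bp differed by -0.26 in ICOS-negative and 2.545 in ICOS-positive cells, Ptgdr2 by 0.145 and 2.535, and Cybb by 2.62 and -0.44. Slc16a5, a monocarboxylate transporter family member, was 2.62-fold lower (log2 difference -1.39, SE 0.17, adjusted p = 0.0128), and Chil5 (-1.30) and the chromatin organiser Satb1 (-1.08) fell too. Smaller falls were those of Mettl1 (-0.79), Gpd2 (-0.70), Mif (-0.69), Dock4 (-0.69), Cks1b (-0.67), Mthfd1 (-0.67) and Prr11 (-0.64).

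In all 28 genes were higher and 13 lower with CD103 in fresh cells, and 117 and 41 without the array that stands apart. With each array left out in turn the total ran from 4, without fresh ICOS single-positive replicate 2, to 158, without either activated ICOS single-positive array. The share higher was 68.3%, and 58.2% after quantile normalization. As a list, the effector Treg genes lay higher (20 of 22 positive, median log2 difference 0.66, adjusted p = 3.33e-09), with 0 passing over all genes and 1 adjusted over the list alone. Their adjusted p = 0.304 with an estimated correlation. When the array that stands apart was also left out, it was 0.0385 for effector Treg, 0.0357 for Treg core, 0.0451 for naive and central and 0.0352 for homing genes. All 20 Treg core genes had positive differences (median 0.37, adjusted p = 3.54e-06, adjusted p = 0.456 with an estimated correlation, 0 passing over all genes and 0 adjusted over the list alone). Of the naive and central genes 15 of 16 had negative differences (median -0.52, adjusted p = 1.51e-10, adjusted p = 0.14 with an estimated correlation), with 1 passing over all genes, Satb1, and 9 falling and 1 rising adjusted over the list alone. Homing and adhesion genes lay higher (21 of 25 positive, adjusted p = 2.25e-07, adjusted p = 0.327 with an estimated correlation), with 0 passing over all genes and 4 adjusted over the list alone. Cell cycle genes lay lower (median -0.32, adjusted p = 9.66e-13, adjusted p = 0.207 with an estimated correlation), with 0 passing over all genes and 8 adjusted over the list alone. This fall lay in ICOS-positive cells. Relative to each gene's mean over all arrays, the list median was -0.72 and -0.54 on the double-positive arrays against 0.04 and 0.25 on the ICOS single-positive ones. It was -1.94 and -2.03 on the CD103 single-positive arrays against -2.04 and -2.25 on the double-negative ones. Also called, and lost with an estimated correlation, were costimulation (adjusted p = 0.00277), suppression (0.0287) and TGF-beta genes (0.0107), which lay higher, and cholesterol synthesis (0.00226) and conventional CD4 activation genes (1.41e-05), which lay lower.

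Of the lists of markers of other cell types, those of myeloid and of B cells were called for CD103 in fresh cells, with 1 gene each passing. The myeloid and dendritic cell list lay higher (16 of 17 positive, median log2 difference 0.39, adjusted p = 8.48e-07, adjusted p = 0.315 with an estimated correlation), with Lyz1 passing over all genes and 2 adjusted over the list alone. The B cell list lay higher (8 of 9 positive, median 0.31, adjusted p = 2.76e-04, adjusted p = 0.354 with an estimated correlation), with Blk passing, and 1 adjusted over the list alone. In ICOS-negative cells 1 array carried the shift: relative to each gene's mean over all arrays, the myeloid median was 0.79 on CD103 single-positive replicate 1 and -0.075 on replicate 2, against 0.16 and -0.087 on the double-negative arrays, and the B cell median was 0.43 and -0.15 against 0.046 and -0.021. In ICOS-positive cells the myeloid median was 0.54 and 0.26 on the double-positive arrays against 0.059 and -0.16 on the ICOS single-positive ones. In the CD8 and NK list, which was not called (adjusted p = 0.461, with a median of -0.004 and a test pointing up), Cd8a passed, and 1 adjusted over the list alone. Its level was 7.78 and 8.05 on the CD103 single-positive arrays and 6.56 or less on the other fresh arrays. Cd8b1, its partner chain, lay between 8.40 and 8.95 on all fresh arrays.

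The CD103 difference depended on ICOS for 9 genes in fresh cells, 5 with a more positive difference in ICOS-positive cells and 4 with a more negative one (30 genes without the array that stands apart). Single fresh arrays end the calls: limma called 0 genes without double-negative replicate 2, CD103 single-positive replicate 2 or either ICOS single-positive array, and 2 without double-positive replicate 1, while 989 genes had an unadjusted p below 0.05 on all arrays. The differences themselves moved little, with Cybb from -3.245 to -2.87, Abi3bp from 2.515 to 3.09 and Ptgdr2 from 2.20 to 2.58 over the arrays left out. Cybb was highest in CD103 single-positive cells: its mean log2 level was 8.30 ± 0.26 (SD, n = 2) in double-negative, 10.92 ± 0.11 in CD103 single-positive, 9.71 ± 0.01 in ICOS single-positive and 9.28 ± 0.11 in double-positive cells (interaction -3.06, SE 0.34, adjusted p = 0.0165). Noxa1, an activator of NADPH oxidase (-1.60), and Cd8a (-1.42) were highest in CD103 single-positive cells too. The calcium channel gene Cacna1d (-1.54) was highest in ICOS single-positive cells. Abi3bp (interaction 2.80, SE 0.28, adjusted p = 0.012), Ptgdr2 (2.39), Kcnk1 (1.52), Sdc1 (1.48) and Slc27a6 (1.19) were highest in double-positive cells, where Ptgdr2 reached 8.75 ± 0.18 against 6.14 to 6.29 in the other fresh subsets. The share more positive was 55.6%, and 41.7% after quantile normalization.

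The follicular list was lower in that interaction (12 of 13 negative, median -1.01, adjusted p = 1.08e-08, adjusted p = 0.0391 with an estimated correlation), with 0 passing over all genes and 4 adjusted over the list alone. The cell cycle list was lower as well (26 of 26 negative, median -0.85, adjusted p = 3.56e-27, adjusted p = 0.123 with an estimated correlation), with 0 passing over all genes and 22 adjusted over the list alone.

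Fresh double-positive cells carried more effector Treg message and less naive and central message than double-negative cells. Klrg1 was 83.4-fold higher (log2 difference 6.38, SE 1.02, adjusted p = 0.00522) and Ccr2 38.5-fold (5.27, SE 1.08, adjusted p = 0.02). Il10 was higher by 4.94 (SE 1.20, adjusted p = 0.0456), with 4.19 and 4.86 on the double-negative arrays, and passed in 4 of 16 fits with 1 array left out. Igfbp4, which is among the naive and central genes, was 16.8-fold lower (log2 difference -4.07, SE 0.79, adjusted p = 0.0146). Of 22 effector Treg genes 16 rose, or 20 adjusted over the list alone (adjusted p = 1.38e-26, adjusted p = 0.138 with an estimated correlation), and of 16 naive and central genes 11 fell, or 14 with 1 rising adjusted over the list alone (adjusted p = 1.48e-12, adjusted p = 0.14 with an estimated correlation).

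Other rises in double-positive cells were Havcr2 (log2 difference 4.61), Gcnt1 (4.43), Gzmb (4.30), Ttc39c (4.30), Fgl2 (4.19), S100a6 (4.19) and Prdm1 (4.06). Gzmb differed by 2.33 in the replicate 1 arrays and by 6.27 in the replicate 2 arrays. Other falls were Dapl1 (-3.96), Treml2 (-3.29), Arhgap20 (-3.28), Atp1b1 (-3.22), Bach2 (-2.68), Gsta4 (-2.58), Bcl2 (-2.57), St8sia6 (-2.53) and the ganglioside synthase gene St8sia1 (-2.39). In all 587 genes were higher and 205 lower, and 784 and 303 without the array that stands apart. The total of 792 fell to 295 and 367 without double-positive replicates 2 and 1 and to 297 and 476 without double-negative replicates 2 and 1. Of 26 cell cycle genes 16 rose, or 23 adjusted over the list alone (adjusted p = 2.85e-40, adjusted p = 0.0695 with an estimated correlation). Of 25 homing and adhesion genes 11 rose, or 18 with 1 falling adjusted over the list alone (adjusted p = 1.46e-16, adjusted p = 0.14 with an estimated correlation). Without the array that stands apart the values with an estimated correlation were 0.0157 for effector Treg, homing and suppression, 0.0401 for naive and central, 0.0385 for cell cycle and 0.0483 for costimulation genes.

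Markers of other cell types were also called higher in double-positive than in double-negative cells, those of myeloid and dendritic cells (13 of 17 positive, median 0.36, 2 passing, Lyz1 at 1.92 and Xcr1 at 0.66, adjusted p = 3.15e-04) and of B cells (7 of 9 positive, median 0.18, 1 passing, Blk at 2.49, adjusted p = 0.021). They were lost with an estimated correlation (0.412 and 0.492). So were Treg core (adjusted p = 0.00108), helper lineage (0.0331), costimulation (8.73e-07), suppression (1.76e-08) and glycolysis genes (0.00209), which were called higher too.

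The fresh single-positive subsets differed in cell cycle genes. Ccna2 was 19.8-fold lower in CD103 single-positive than in ICOS single-positive cells (probe set 10497831, log2 difference -4.31, SE 0.17, adjusted p = 7.14e-07), and Mki67 13.3-fold lower (-3.74, SE 0.21, adjusted p = 9.08e-06). Of 26 cell cycle genes 24 were lower, or 26 adjusted over the list alone (median -1.94, adjusted p = 2.49e-66, adjusted p = 0.0391 with an estimated correlation). Il21, a cytokine of helper cells, was lower (log2 difference -4.39, SE 0.84, adjusted p = 0.019), with a level of 8.94 to 9.27 on the ICOS single-positive arrays and 4.65 to 5.13 on the other fresh arrays.

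Also lower in CD103 single-positive cells were Ccnb2 (log2 difference -3.69), Bub1 (-3.57), S100a6 (-3.46), Kif11 (-3.45), E2f8 (-3.31), Rrm2 (-3.29) and Top2a (-3.07). Higher were Arhgap20 (3.35, SE 0.38, adjusted p = 5.54e-04), Khdc1a (2.37), the adhesion receptor Adgrg1 (2.13), Gata1 (2.11), Ddx43 (2.07), Treml2 (2.06), Gsta4 (1.97), Cnksr3 (1.87), the carnitine transporter Slc22a5 (1.86) and St8sia6 (1.79). In all 133 genes were higher and 356 lower, and 213 and 440 without the array that stands apart. The total of 489 fell to 206 and 254 without ICOS single-positive replicates 2 and 1 and to 279 and 291 without CD103 single-positive replicates 2 and 1. Of 9 genes of activated conventional CD4 T cells 3 were lower, Il21, Il2 (-2.82) and Cd40lg (-1.31), or 4 adjusted over the list alone (adjusted p = 8.48e-07, adjusted p = 0.14 with an estimated correlation). The helper lineage list was lower (2 of 13 passing, 5 adjusted over the list alone, adjusted p = 3.73e-06, adjusted p = 0.174 with an estimated correlation), with Il12rb2 at -2.86. Also lower were effector Treg (adjusted p = 4.16e-11), homing (1.34e-05), follicular (9.34e-05), costimulation (0.0119), suppression (3.83e-04), glycolysis (3.81e-06) and cholesterol synthesis genes (3.88e-04), and TGF-beta genes were higher (0.031). With an estimated correlation these were lost, and without the array that stands apart as well it was 0.0385 for effector Treg, 0.0401 for homing and follicular and 0.0157 for cell cycle genes.

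The suppression assay changed more genes than any subset comparison. Il12rb2, a chain of the IL-12 receptor, was 42.5-fold higher in activated than in fresh cells over the 4 subsets (probe set 10545135, log2 difference 5.41, SE 0.25, adjusted p = 5.20e-08), and the chemokine Ccl3 22.4-fold (4.48, SE 0.49, adjusted p = 3.62e-05). Ccr9, a gut homing chemokine receptor, was 18.4-fold lower (probe set 10590620, log2 difference -4.21, SE 0.22, adjusted p = 1.30e-07). All 26 cell cycle genes rose, and all 26 adjusted over the list alone (median log2 difference 2.64, adjusted p = 3.81e-31, adjusted p = 0.108 with an estimated correlation, and 0.0451 without the array that stands apart as well).

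Further rises with activation were Mt2 (log2 difference 4.41), the steroidogenic enzyme Cyp11a1 (4.31), Ak4 (4.26), the granule protease Gzma (4.05), the mitotic kinase Bub1 (3.94), Bnip3 (3.86), Lilr4b (3.75) and Ermn (3.59). Further falls were Dtx1 (-3.49), Cybb (-3.38), Klf3 (-2.96), Prg4 (-2.95), Ifi208 (-2.90), St8sia6 (-2.89), Slc9a9 (-2.72), H2-Ob (-2.63) and Ttc28 (-2.62). In all 2870 genes were higher and 3344 lower, and 2836 and 3276 without the array that stands apart. The share higher depended on the scaling, with 46.2% on the deposited values, 60.6% after quantile normalization, 65% after median centring and 56.6% after cyclic loess, and was 59.2% among the 1069 genes with an absolute log2 difference of at least 1.

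Metabolic genes rose together with activation. Of 13 glycolysis genes 12 rose, and 12 adjusted over the list alone, among them Slc16a3 (log2 difference 3.12), Hk2 (2.85), Tpi1 (2.49) and Pgk1 (1.98), with adjusted p = 2.12e-11 and adjusted p = 0.14 with an estimated correlation. Of 16 cholesterol synthesis genes 14 rose, or 15 adjusted over the list alone, among them Idi1 (2.56), Sqle (1.95), Fdps (1.65) and Cyp51 (1.63), with adjusted p = 3.68e-11 and adjusted p = 0.14 with an estimated correlation. Of 15 interferon response genes 10 fell, and 10 adjusted over the list alone, among them Ifit3 (-2.21), Ifit1 (-1.90) and Oasl2 (-1.10), with adjusted p = 0.00122 and adjusted p = 0.207 with an estimated correlation. Of 17 TGF-beta pathway genes 11 fell and 2 rose, and the same adjusted over the list alone, among them the receptor genes Tgfbr1 (-1.72) and Tgfbr2 (-1.25) and Smad3 (-0.83), with adjusted p = 2.32e-05 and adjusted p = 0.198 with an estimated correlation.

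Effector and helper genes also rose with activation. Of 22 effector Treg genes 12 rose and 2 fell, or 13 and 2 adjusted over the list alone, among them Gzmb (log2 difference 3.47), Bhlhe40 (2.59), Nfil3 (2.29) and Il10 (2.17), with adjusted p = 9.49e-04 and adjusted p = 0.51 with an estimated correlation. Of 13 helper lineage genes 8 rose and 2 fell, or 9 and 2 adjusted over the list alone, among them Il5 (3.34), Il13 (3.02) and Il17f (2.46), with adjusted p = 0.00298 and adjusted p = 0.355 with an estimated correlation. Of 16 naive and central genes 8 fell and 1 rose, and the same adjusted over the list alone, with Il6ra (-1.77), Il6st (-1.42) and Foxp1 (-1.40) lower and Satb1 higher (1.43), with adjusted p = 5.16e-04 and adjusted p = 0.374 with an estimated correlation. Of 25 homing and adhesion genes 12 fell and 4 rose, or 12 and 5 adjusted over the list alone, with Itga4 (-2.39), Cxcr5 (-2.10) and Ccr6 (-2.05) lower, and adjusted p = 0.0357 for the list. With an estimated correlation its adjusted p = 0.631, and without the array that stands apart its adjusted p = 0.326. The Treg core list was not called (5 rose, 5 fell of 20, and the same adjusted over the list alone, adjusted p = 0.905), with Nrp1 (-2.53), Nt5e (-2.23) and Ikzf2 (-0.95) lower and Tigit higher (0.95).

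After activation ICOS-positive cells carried more message of the IL-17 cytokines. Il17a was 13.2-fold higher than in ICOS-negative cells (probe set 10345032, log2 difference 3.72, SE 0.68, adjusted p = 0.0114) and Il17f 5.5-fold (2.46, SE 0.49, adjusted p = 0.016). The mean log2 level of Il17a was 6.53 ± 0.58 (SD, n = 2) in double-negative, 6.24 ± 0.35 in CD103 single-positive, 8.61 ± 3.10 in ICOS single-positive and 11.59 ± 0.04 in double-positive cells. The Il17a difference was 4.81 without the array that stands apart (adjusted p = 2.07e-06). Klrg1 was 7.02-fold higher (2.81, SE 0.72, adjusted p = 0.041), and on the log2 scale 3.98 without that array and 1.64 without its partner. It passed in 2 of 16 fits with 1 array left out.

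Also higher with ICOS in activated cells were Frmd5 (log2 difference 2.59), Cxcl3 (2.47), Cxcr6 (2.39), Iltifb (2.30), whose sequence is close to that of Il22, and the related Ifi209 (2.28), Ifi206 (2.13) and Ifi213 (2.13), whose probes can share signal. Lower were the cytokine Il24 (-3.02, SE 0.41, adjusted p = 0.00419), the transglutaminase Tgm2 (-2.69), Stra6 (-2.63), the actin severing gene Scin (-2.49), the lipid desaturase Scd1 (-2.38), Pth (-2.32), Plk2 (-2.27), Cyp11a1 (-2.20), Efna5 (-2.19) and Map3k20 (-2.12). The fall of Scin no longer passed without the array that stands apart (-2.03, adjusted p = 0.0818). In all 387 genes were higher and 996 lower, and 560 and 765 without that array. The total of 1383 fell to 443 with only the activated arrays and to 509 without activated double-positive replicate 2. The share higher was 28%, 41.3% after quantile normalization and 39.7% after cyclic loess, and the balance turned among the genes with an absolute log2 difference of at least 1, with 100 higher and 68 lower.

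Of 15 interferon response genes 7 rose with ICOS in activated cells, or 9 adjusted over the list alone, among them Ifit1 (log2 difference 2.05), Rtp4 (1.93), Irf7 (1.49) and Gbp3 (1.08), with adjusted p = 4.11e-07 and adjusted p = 0.119 with an estimated correlation. Of 16 cholesterol synthesis genes 6 fell, or 10 adjusted over the list alone, among them Lss (-1.03), Idi1 (-0.71) and Sqle (-0.66), with adjusted p = 9.36e-08 and adjusted p = 0.198 with an estimated correlation. Of 26 cell cycle genes 8 fell, or 16 adjusted over the list alone, among them Tyms (-0.68) and Mcm7 (-0.64), with adjusted p = 2.93e-09 and adjusted p = 0.287 with an estimated correlation. Of these 26 genes 2 fell without the array that stands apart. Of 25 homing and adhesion genes 6 rose, or 11 with 1 falling adjusted over the list alone, among them Cxcr3 (1.41), Gcnt1 (1.33) and Cxcr5 (0.89), with adjusted p = 2.72e-05 and adjusted p = 0.386 with an estimated correlation. The effector Treg list was not called (4 of 22 rose, 5 with 1 falling adjusted over the list alone, adjusted p = 0.0677). Without the array that stands apart 10 rose and 1 fell, with adjusted p = 2.33e-06 for the list and adjusted p = 0.15 with an estimated correlation. Homing genes then had 0.0324. Also called, and lost with an estimated correlation, were helper lineage (adjusted p = 0.0127), follicular (0.00586), costimulation (0.0279), conventional CD4 activation (0.0139) and myeloid genes (0.0241), which lay higher, and glycolysis genes (2.02e-04), which lay lower. Myeloid genes no longer passed without that array (0.0605).

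CD103 marked fewer genes than ICOS in activated cells as well. Bach2 was 5.26-fold lower in the CD103-positive subsets (probe set 10503695, log2 difference -2.40, SE 0.36, adjusted p = 0.0188) and St8sia1 6.95-fold lower (probe set 10549162, -2.80, SE 0.37, adjusted p = 0.0114). Their differences were -1.98 and -2.20 without the array that stands apart. Il24 was 4.93-fold higher (2.30, SE 0.41, adjusted p = 0.0363), but did not pass without that array (2.25). The kinase gene Map3k20 was 3.39-fold higher (1.76, SE 0.17, adjusted p = 0.00258). The IL-1 receptor antagonist Il1rn was 3.81-fold higher (1.93, SE 0.36, adjusted p = 0.0421, failing without that array). With 1 array left out they passed in 4 (Il24), 16 (Map3k20) and 3 (Il1rn) of 16 fits.

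Also higher with CD103 in activated cells were Plcd1 (log2 difference 2.25), Jcad (1.71), Edil3 (1.503), the matrix proteoglycan Lum (1.44), the fatty acid binding protein Fabp5 (1.34), Avpi1 (1.28) and Fzd7 (1.20). With 1 array left out Plcd1 and Fabp5 passed in 2 of 16 fits. Without the array that stands apart Jcad (1.40) and Fzd7 (1.15) no longer passed. Lower were the phosphodiesterase Pde3b (-2.13), Ms4a4b (-2.12), Ifi208 (-1.98), Ifi214 (-1.98), Tmem71 (-1.97), Trim12a (-1.73), Ifi213 (-1.61) and Evl (-1.59). Pde3b passed in 2 of 16 such fits, and not without that array (-1.67). In all 40 genes were higher and 103 lower, and 24 and 48 without it. With only the activated arrays, where fewer arrays estimate the spread, limma called 0 genes, while 2414 had an unadjusted p below 0.05 on all arrays, and with each array left out in turn the total ran from 23, without activated double-positive replicate 2, to 942, without activated ICOS single-positive replicate 1. The share higher was 28%, 40.1% after quantile normalization and 39.3% after median centring. The naive and central list lay lower (2 of 16 passing, Bach2 and Foxp1, and 8 adjusted over the list alone, adjusted p = 1.34e-10, adjusted p = 0.14 with an estimated correlation). The Treg core list was called higher (17 of 20 positive, 0 passing over all genes and 0 adjusted over the list alone, adjusted p = 0.0048, adjusted p = 0.631 with an estimated correlation), and lay the other way without the array that stands apart (adjusted p = 0.713). Also called, and lost with an estimated correlation, were effector Treg (adjusted p = 0.00591, and 0.108 without that array), glycolysis (1.48e-04) and cholesterol synthesis genes (0.00576), which lay higher, and immediate early (7.39e-04) and interferon response genes (0.0131), which lay lower.

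The interaction of CD103 and ICOS after activation held 3 genes: Lum (3.57, SE 0.44, adjusted p = 0.0399), Ifi213 (-2.07) and Card6 (-1.66). Lum, a matrix proteoglycan, had a mean log2 level of 8.17 ± 0.30 (SD, n = 2) in activated double-positive cells and of 4.38 to 4.95 in the other activated subsets. Ifi213 was highest in ICOS single-positive cells, at 9.39 ± 0.11 against 5.64 to 6.74. Without the array that stands apart limma called 0 genes, though the differences stayed near their size, at 3.06 (SE 0.36, adjusted p = 0.126) for Lum, -1.99 (SE 0.28, adjusted p = 0.173) for Ifi213 and -1.48 (SE 0.20, adjusted p = 0.173) for Card6. With a replicate block it also called 0 (adjusted p = 0.0594 for each of them), and 518 genes had an unadjusted p below 0.05 on all arrays.

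Activated double-positive cells had 12.8-fold less Bach2 than activated double-negative cells (log2 difference -3.68, SE 0.51, adjusted p = 0.0434) and more Lum (3.44, SE 0.31, adjusted p = 0.00289), with 4.34 and 5.11 on the double-negative arrays. Adgrl2 (2.16), Hey1, a target of Notch signalling (1.41), Nid2 (1.40) and Akap6 (1.39) were higher, and Eno3 (-2.74), the prion protein gene Prnp (-1.51) and Tex15 (-1.42) lower. These 5 higher and 4 lower genes were all that passed, against 191 and 146 without the array that stands apart. With only the activated arrays limma called 0 genes, while 3028 had an unadjusted p below 0.05 on all arrays. With a replicate block on all arrays 118 genes were higher and 122 lower. The array that stands apart is in neither group and enters through the shared estimate of the spread. The share higher was 55.6%, and 77.8% after quantile normalization. The homing and adhesion list was higher (23 of 25 positive, 0 passing over all genes and 8 adjusted over the list alone, adjusted p = 4.64e-06, adjusted p = 0.368 with an estimated correlation, and 0.0385 when that array was also left out). Also called, and lost with an estimated correlation, were effector Treg (adjusted p = 3.37e-04), suppression (0.014) and interferon response genes (0.00558), which lay higher, and naive and central (0.0127), cell cycle (1.79e-06), immediate early (0.00352) and cholesterol synthesis genes (0.00591), which lay lower.

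The ICOS difference in cell cycle genes was smaller after activation than before. Mki67 rose from 6.56 ± 0.49 (SD, n = 2) to 11.67 ± 0.10 in double-negative cells and from 10.79 ± 0.09 to 11.46 ± 0.12 in ICOS single-positive cells, and the ICOS difference changed by -3.93 (SE 0.21, adjusted p = 5.70e-06). The change for Ccna2 was -3.94 (SE 0.17, adjusted p = 1.57e-06). All 26 cell cycle genes had a lower ICOS difference after activation, and all 26 adjusted over the list alone (median -2.19, adjusted p = 1.51e-45, adjusted p = 0.0587 with an estimated correlation, and 0.0324 without the array that stands apart as well).

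In all the ICOS difference was higher after activation for 411 genes and lower for 928, and for 390 and 790 without the array that stands apart. The total of 1339 fell to 815 without fresh ICOS single-positive replicate 2. Besides the cell cycle genes Bub1 (-3.75) and Kif11 (-3.58), it was lower for Sccpdh (-3.52), and for 4 of 22 effector Treg genes, Ccr8 (-2.32), Id2 (-1.76), Batf (-1.47) and Irf4 (-1.46). Adjusted over the list alone 14 effector Treg genes were lower, with adjusted p = 1.10e-09 for the list and adjusted p = 0.287 with an estimated correlation. It was higher for Ifi206 (2.77), Ifi213 (2.64), St8sia6 (2.53), Ifi214 (2.50) and Slc28a2b (2.48). Of the interferon response genes 4 of 15 were higher, Ifit1 (2.44), Irf7 (1.69), Oasl2 (0.99) and Oasl1 (0.93), or 8 adjusted over the list alone, with adjusted p = 8.51e-05 for the list and adjusted p = 0.14 with an estimated correlation. Of the naive and central genes 5 of 16 were higher, among them Klf2 (2.29), Id3 (1.69), S1pr1 (1.60) and Pecam1 (1.27), or 7 adjusted over the list alone, with adjusted p = 5.56e-07 for the list and adjusted p = 0.227 with an estimated correlation.

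The CD103 difference changed with activation for fewer genes, 21 higher and 38 lower, and 19 and 45 without the array that stands apart. With each array left out in turn the total ran from 8, without fresh ICOS single-positive replicate 2, to 366, without activated ICOS single-positive replicate 1. It was higher after activation for Map3k20 (1.63, SE 0.25, adjusted p = 0.028), the cytokine Lif (1.55), Hey1 (1.48), Slc16a5 (1.39) and Edil3 (1.38), and lower for Card6 (-1.74, SE 0.15, adjusted p = 0.00243), Ephx1 (-1.98), Tmem71 (-1.93), Ipcef1 (-1.91) and Cd101 (-1.88). Cd101 was 1.24 higher with CD103 in fresh cells and at a mean of 6.99 to 7.21 in the activated subsets other than ICOS single-positive, where it was 8.19. Hexokinase Hk2 (1.27) was the 1 glycolysis gene that passed, with 2 adjusted over the list alone (adjusted p = 1.98e-04, adjusted p = 0.368 with an estimated correlation). The share higher was 35.6%, 48.8% after quantile normalization and 58.3% after median centring.

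**Figure D2:**
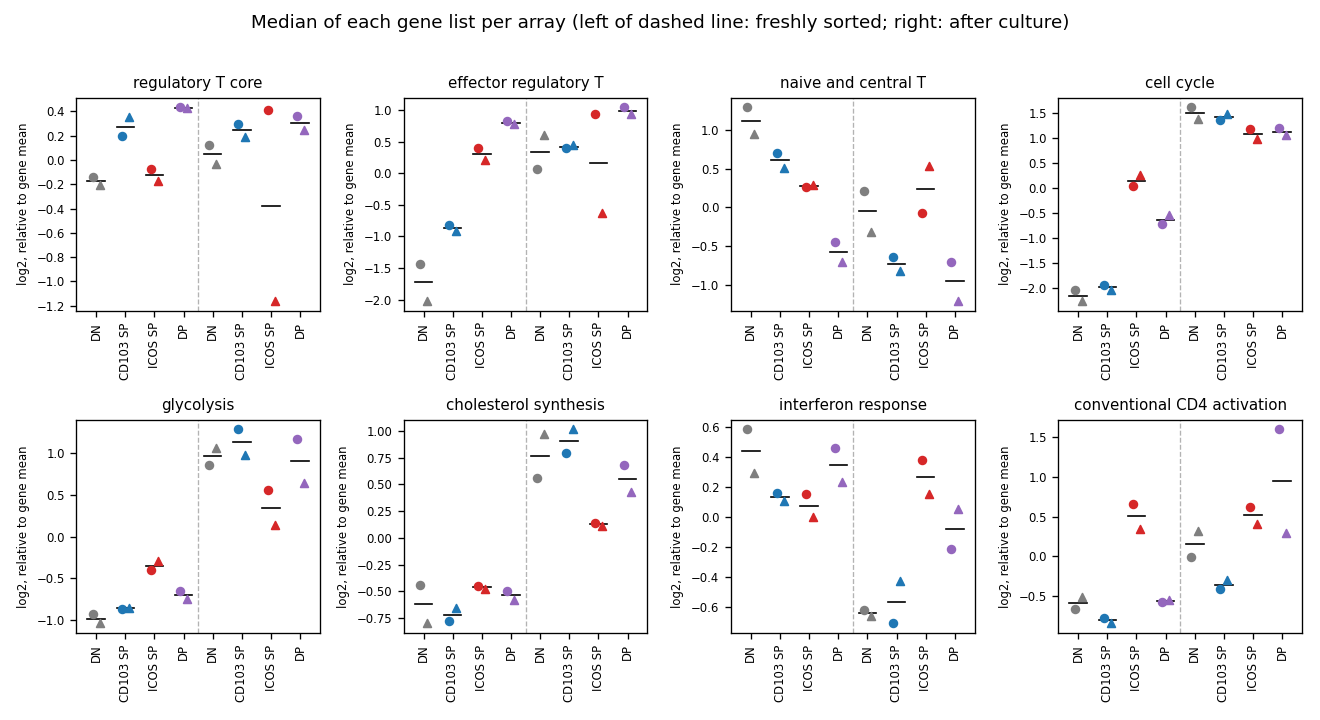
Median over the members of 8 gene lists of the log2 intensity relative to each gene's mean over all arrays (vertical axis), in the 4 subsets, fresh to the left of the dashed line and activated to the right. Circles are replicate 1 arrays, triangles replicate 2 arrays and black lines group means (n = 2). The cell cycle medians of fresh ICOS-positive arrays lie above those of fresh ICOS-negative arrays, with a median difference of 1.61, and 1 activated ICOS single-positive array lies low in the Treg core list.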

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

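The tests of a difference between differences below were planned before the data were examined. The tests of technical explanations and of other splits of the arrays were chosen after the results were seen.

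The CD103 difference depended on ICOS for 9 genes in fresh cells and for 3 in activated cells. The CD103 difference changed with activation for 59 genes and the ICOS difference for 1339. In fresh cells the interaction was a log2 difference of 2.80 for Abi3bp, 2.39 for Ptgdr2, 1.52 for Kcnk1, 1.48 for Sdc1, 1.19 for Slc27a6, -1.42 for Cd8a, -1.54 for Cacna1d, -1.60 for Noxa1 and -3.06 for Cybb. In activated cells it was a log2 difference of 3.57 for Lum, -1.66 for Card6 and -2.07 for Ifi213.

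The CD103 difference changed with activation by a log2 difference of 1.63 for Map3k20, 1.55 for Lif, 1.48 for Hey1, 1.39 for Slc16a5, 1.38 for Edil3, 1.27 for Hk2, -0.70 for Cd8a, -1.74 for Card6, -1.88 for Cd101, -1.91 for Ipcef1, -1.93 for Tmem71 and -1.98 for Ephx1. The ICOS difference rose with activation by a log2 difference of 2.77 for Ifi206, 2.64 for Ifi213, 2.53 for St8sia6, 2.50 for Ifi214, 2.48 for Slc28a2b, 2.44 for Ifit1, 2.29 for Klf2, 1.69 for Irf7, 1.69 for Id3, 1.60 for S1pr1, 1.57 for Itga4, 1.27 for Smad7, 1.27 for Pecam1, 0.99 for Oasl2, 0.93 for Oasl1, 0.79 for Skil, 0.67 for Cd8a and 0.60 for Tgfbr2. It was lower after activation by a log2 difference of -0.89 for Hmgcs1, -0.91 for Hsp90aa1, -1.002 for Blk, -1.02 for Slc16a3, -1.08 for Idi1, -1.15 for Lif, -1.17 for Tpi1, -1.25 for Stard4, -1.25 for Hspd1, -1.27 for Lgals1, -1.29 for Pgam1, -1.39 for Hk2, -1.46 for Irf4, -1.47 for Batf, -1.53 for Ahr and -1.76 for Id2. The larger falls were a log2 difference of -2.02 for Gcnt1, -2.32 for Ccr8, -2.94 for Ccr3, -3.52 for Sccpdh, -3.58 for Kif11, -3.75 for Bub1, -3.93 for Mki67 and -3.94 for Ccna2. The sort gene Icos, read as a check, had -1.46.

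Lists differed in the same 4 tests. For the interaction in fresh cells the list adjusted p was 0.0179 for effector Treg, 0.0101 for helper lineages, 1.08e-08 for follicular, 3.56e-27 for cell cycle, 2.72e-05 for glycolysis, 3.60e-05 for interferon response and 5.34e-04 for conventional CD4 activation. In activated cells it was 1.98e-04 for Treg core, 7.67e-04 for effector Treg, 2.37e-07 for naive and central, 0.013 for homing, 0.00397 for cell cycle, 0.0241 for suppression, 0.00175 for glycolysis, 3.34e-05 for cholesterol synthesis, 2.67e-05 for interferon response and 2.63e-06 for conventional CD4 activation. Without the array that stands apart the activated interaction turned direction for Treg core (adjusted p = 7.23e-04), effector Treg (0.232) and homing (0.201), and cell cycle (0.439), suppression (0.935) and glycolysis (0.209) no longer passed. For the CD103 difference and activation it was 0.0249 for homing, 1.05e-06 for cell cycle, 0.0195 for immediate early genes, 0.00226 for costimulation, 0.0419 for the TGF-beta pathway, 1.98e-04 for glycolysis, 8.33e-05 for cholesterol synthesis and 5.05e-04 for myeloid markers. For the ICOS difference and activation it was 1.10e-09 for effector Treg, 5.56e-07 for naive and central, 0.0107 for homing, 1.51e-45 for cell cycle, 0.00789 for suppression, 2.25e-07 for glycolysis, 8.48e-07 for cholesterol synthesis and 8.51e-05 for interferon response. Of all these, the follicular list in fresh cells alone holds with an estimated correlation (adjusted p = 0.0391). When the array that stands apart was also left out, it was 0.0157 for that list, 0.0473 for costimulation with the CD103 difference and 0.0324 for the cell cycle with the ICOS difference.

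The activated ICOS single-positive replicate 2 array stands apart from its partner. Its naive and central T cell genes lie 0.472 (median log2) above the partner, but normalized values cannot test an array-wide loss of signal. Foxp3 is at least 11.69 on every other array, but an exchange of labels within the series would only move the low value to another label. So Foxp3 cannot test an exchange. Icos was 11.25 on this array, against 11.63 to 12.12 on the activated ICOS-negative arrays, and Klrg1 was 5.32, against 5.35 to 7.44. Whether labels were exchanged was not tested. A candidate explanation is that this sample held mostly conventional CD4 T cells, which fits a Treg core median of -1.853 against the partner. Klrd1 (10.47 against 5.32), Klrc1 (8.75 against 4.83) and Klrk1 (8.36 against 5.01), receptors of NK and CD8 T cells, were higher on it, while Cd8a (6.11 against 5.95) and Ncr1 (4.74 against 4.79) lay near the partner. Which cells carry these receptors was not tested. The re-sort on cells lacking the congenic marker would remove the naive cells added to the culture, so such cells would need to come from the sorted subset or to have passed the gate. Treg that lost Foxp3 in culture, or a swap with a sample inside or outside the series, stay open and were not tested.

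Fresh ICOS single-positive arrays carried cytokine genes that the other fresh arrays carried less of: Il21 at 8.94 to 9.27 against 4.65 to 5.13, Il2 at 8.35 to 8.67 against 5.67 to 6.36, Ifng at 8.37 to 8.42 against 6.73 to 7.06, and Cd40lg at 8.90 to 8.99 against 7.57 to 8.26. Carry-over of B cells and myeloid cells is argued against, since the median of their markers was -0.281 relative to the other fresh arrays. Conventional CD4 T cells inside the sorting gate may add to these genes. Foxp3 was -0.350 relative to the mean of the other fresh arrays, and its range of 11.99 to 12.34 overlaps theirs of 12.16 to 12.84. Among arrays of the same replicate number it was lowest in ICOS single-positive cells (12.34 against 12.56 to 12.84, and 11.99 against 12.16 to 12.50), and Il2ra was 12.18 to 12.24 against 12.53 to 12.67 on the other fresh arrays. Such cells would lower both genes, and so would Treg of this subset with less of both, so these cells and a cytokine programme of ICOS single-positive Treg cannot be told apart. The latter is the difference the design names and was not tested apart from the sort.

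The ICOS difference of the interferon response list rose on activation, by a median log2 of 0.518. Relative to each gene's mean over all arrays, the list median fell in the ICOS-negative subsets, from 0.585 and 0.295 to -0.618 and -0.656 in double-negative and from 0.163 and 0.107 to -0.705 and -0.426 in CD103 single-positive cells. It fell less in double-positive cells, from 0.461 and 0.235 to -0.213 and 0.055, and was 0.154 and -0.001 before and 0.381 and 0.153 after in ICOS single-positive cells. So the change lies mostly in a fall in ICOS-negative cells. The array that stands apart is argued against as the whole cause, since the median was 0.646 without it. The scaling is argued against as the whole cause, since the lowest median over the other scalings was 0.455. The list is lost with an estimated correlation (adjusted p = 0.14), and the list tests over its alternatives run from that value to 4.78e-06 without the array that stands apart. A difference between the ICOS subsets in their response to the culture may account for it and stays an untested hypothesis.

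Other splits of the arrays were fitted with the arrays of the compared groups in 2 sets, or with their interaction, which differs from the test over 8 groups, so their counts differ from those above. The splits treat the arrays as exchangeable and ignore the replicate number. Chance is excluded at the 0.05 level for the ICOS comparison in activated cells (1 of 35 splits as large, 679 genes, highest other 8). Activation passes that level too (1 of 100 splits, 5552 genes, highest other 1). For the change of the ICOS difference with activation the share was below 0.05 (2 of 100 splits, 859 genes). But another split gave 1003 genes, more than the labels did, so chance is not called excluded there. For the ICOS comparison in fresh cells chance is not excluded (2 of 35 splits, 1168 genes, highest other 1279). The split with 1279 genes is the one by replicate number, the 1 other split that called any gene, and with the replicate number as a block the ICOS comparison gave 2275 genes. For 5 other results the fit in 2 sets called 0 genes, so every split counts as large by construction and the splits say nothing about chance. In fresh cells these are the CD103 comparison and the interaction (35 of 35 splits each, highest other 1279). In activated cells they are the same 2 (35 of 35 each, highest other 679). The last is the change of the CD103 difference with activation (100 of 100, highest other 584). Beside these counts of 0, limma with 8 groups called 41, 9, 143, 3 and 59 genes, and 1494, 989, 2414, 518 and 2111 genes had an unadjusted p below 0.05 in it. The highest other splits point to a structure of the samples, by replicate number in fresh cells and by ICOS in activated cells.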

How the results depend on the processing

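The block, the filter and the list tests without the activated ICOS single-positive replicate 2 array were chosen after seeing the data, and the other alternatives before. Below, the comparisons are named fresh CD103, fresh ICOS, fresh interaction, fresh double-positive (against double-negative), fresh single-positives, activated CD103, activated ICOS, activated interaction, activated double-positive, activation, CD103 change and ICOS change, with counts of genes. The main counts are 41, 1301, 9, 792, 489, 143, 1383, 3, 9, 6214, 59 and 1339. The cause of a change was not tested, except that fewer or more genes or arrays enter by construction.

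With a replicate block the counts were 143, 2275, 71, 1412, 1018, 519, 2734, 0, 240, 7515, 370 and 2638 in that order, and without the array that stands apart as well 531, 2815, 194, 1959, 1431, 272, 2763, 0 and 1116, then 432 and 2438 for the CD103 and ICOS changes. The replicate 1 minus replicate 2 differences of different groups correlated across genes above 0.1 in 6 of 6 pairs of fresh groups (0.499 to 0.752), 6 of 6 pairs of activated groups (0.114 to 0.450) and 15 of 16 pairs across states (-0.016 to 0.424), and genes are not independent replicates. The labels give the arrays a shared number and no more. Beside the 0 of the activated interaction, 518 genes had an unadjusted p below 0.05 in limma without the block.

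With only the arrays of the state, fresh CD103 gave 268, fresh interaction 62, fresh double-positive 1264, fresh single-positives 787, activated CD103 0, activated ICOS 443, activated interaction 0 and activated double-positive 0, where fewer arrays estimate the spread. The dim-gene filter gave 14 for activated double-positive, and without the array that stands apart 175 for fresh CD103, 27 for fresh interaction, 89 for activated CD103, 1 for activated interaction and 335 for activated double-positive. Quantile normalization gave 0 for activated interaction and 18 for activated double-positive, median centring 0, 19 and 36 for CD103 change, and cyclic loess 0, 26 and 132. The intensity trend gave 28 for fresh interaction and 29 for activated double-positive. Array weights gave 21 and the mean of probe sets 17 for fresh interaction. All probe sets gave 22 for fresh CD103, 2 for fresh interaction, 0 for activated interaction, 11067 for activation and 21 for CD103 change. A minimum absolute log2 difference of 1 left 13 for fresh CD103, 416 for fresh ICOS, 478 for fresh double-positive, 289 for fresh single-positives, 56 for activated CD103, 168 for activated ICOS, 1069 for activation, 39 for CD103 change and 570 for ICOS change.

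With each array left out, the lone array of its group is assumed to vary like the others. Fresh CD103 ran from 4 to 158: 4 and 8 without fresh ICOS single-positive replicates 2 and 1, 7 and 11 without fresh double-negative replicates 1 and 2, 10 without fresh CD103 single-positive replicate 1, 12 and 10 without fresh double-positive replicates 1 and 2, 27 without either activated CD103 single-positive array and 158 without either activated ICOS single-positive array. Fresh ICOS ran from 771 to 1558: 771 and 789 without fresh ICOS single-positive replicates 2 and 1, 851 without fresh double-negative replicate 2 and 820 without fresh double-positive replicate 2. Fresh interaction ran from 0 to 30: 0 without fresh double-negative replicate 2, fresh CD103 single-positive replicate 2 or either fresh ICOS single-positive array, 2 without fresh double-positive replicate 1, 16 without either activated double-negative array and 30 without either activated ICOS single-positive array. Fresh double-positive ran from 295 to 1087: 476 and 297 without fresh double-negative replicates 1 and 2, 367 and 295 without fresh double-positive replicates 1 and 2. Fresh single-positives ran from 206 to 653: 291 and 279 without fresh CD103 single-positive replicates 1 and 2, 254 and 206 without fresh ICOS single-positive replicates 1 and 2.

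Activated CD103 ran from 23 to 942: 78 without either fresh double-negative array, 87 without either fresh CD103 single-positive array, 50 without either fresh ICOS single-positive array, 79 without either fresh double-positive array, 62 without activated double-negative replicate 1, 29 without activated CD103 single-positive replicate 1, 942 and 72 without activated ICOS single-positive replicates 1 and 2, 93 and 23 without activated double-positive replicates 1 and 2. Activated ICOS ran from 509 to 1449: 644 without activated double-negative replicate 1, 600 and 897 without activated CD103 single-positive replicates 1 and 2 and 509 without activated double-positive replicate 2. Activated interaction ran from 0 to 201: 201 without activated ICOS single-positive replicate 1, 1 without activated double-negative replicate 2, activated CD103 single-positive replicate 1 or activated double-positive replicate 2, and 0 without any other array. Activated double-positive ran from 4 to 337: 4 without any fresh CD103 single-positive or double-positive array, 23 and 32 without activated double-negative replicates 1 and 2, 19 without activated double-positive replicate 1 and 337 without either activated ICOS single-positive array. Activation ran from 5651 to 6112. CD103 change ran from 8 to 366: 24 and 14 without fresh double-negative replicates 1 and 2, 14 without fresh CD103 single-positive replicate 2, 11 and 8 without fresh ICOS single-positive replicates 1 and 2, 21 and 15 without fresh double-positive replicates 1 and 2, 109 without activated double-negative replicate 2, 22 and 34 without activated CD103 single-positive replicates 1 and 2, 366 without activated ICOS single-positive replicate 1 and 22 without activated double-positive replicate 2. ICOS change ran from 815 without fresh ICOS single-positive replicate 2 to 1663 without activated ICOS single-positive replicate 1.

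The 407 named-gene calls were selected for passing on these arrays, so 0 reversals under any alternative say little. The block kept 404, the arrays of the state alone 173 of 265, and all probe sets 315. The filter kept 391 of 396, quantile normalization 392, median centring 390 and cyclic loess 393. Leaving out some single fresh arrays ended more calls than any of these. The check genes changed sign only where they had not passed. Foxp3 was 0.027 for fresh ICOS with median centring. With the block and with the filter, both without the array that stands apart, Foxp3 was -0.013 and -0.10 for activated CD103, 0.39 and 0.47 for activated ICOS (with adjusted p = 0.0202 in the first), -0.19 and -0.35 for activated interaction, -0.35 and -0.43 for CD103 change and 0.41 and 0.49 for ICOS change. Likewise Il2ra was 0.14 and 0.12 for activated ICOS and -0.13 and -0.11 for CD103 change, Itgae -1.12 and -1.15 for activated interaction and 0.81 and 0.83 for ICOS change, and Icos -0.37 and -0.34 for activated interaction. Il2ra was -0.003 for ICOS change with median centring. With each array left out, Foxp3 ran from -0.12 to 0.074 for fresh ICOS, -0.10 to 1.96 for activated CD103, -1.59 to 0.47 for activated ICOS, -0.35 to 3.76 for activated interaction, -0.43 to 1.63 for CD103 change and -1.56 to 0.49 for ICOS change. Itgae ran from -0.048 to 1.80 for activated ICOS, -1.15 to 2.55 for activated interaction and -1.02 to 0.83 for ICOS change, Il2ra from -0.40 to 0.12 for activated ICOS, -0.11 to 0.42 for CD103 change and -0.20 to 0.32 for ICOS change, and Icos from -0.34 to 1.29 for activated interaction and -0.55 to 0.27 for CD103 change.

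Of 113 list calls, 3 hold with an estimated correlation, 111 with the block, 43 with fry and 100 with the filter. Without the array that stands apart 102 hold, 7 end and 4 reverse. With its absence and an estimated correlation 24 hold, 85 end and 4 reverse. The reversed calls have adjusted p = 0.713 for Treg core in activated CD103, and 0.889 with an estimated correlation as well. In the activated interaction the pairs are 7.23e-04 and 0.228 for Treg core, 0.232 and 0.681 for effector Treg, and 0.201 and 0.507 for homing and adhesion. No scaling moved the median of all genes by more than 0.1 in any comparison. Signal over background limits dim genes: 11635 of the 19938 genes pass the filter.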

Other observations

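Genes of activated conventional CD4 T cells rose in part during the assay. Of 9 such genes 5 rose and 2 fell, and the same adjusted over the list alone, among them Lif (log2 difference 3.26), Il21 (2.001), Il3 (1.68) and Csf2 (1.35), and the list was not called (adjusted p = 0.083). Among costimulation and coinhibition genes Tnfrsf9 (1.54), Havcr2 (1.41) and Lag3 (1.31) rose and Cd226 (-2.27) fell, with 6 of 17 rising and 6 falling, and the same adjusted over the list alone (adjusted p = 0.996). Among follicular genes Cxcr5 (-2.10) and Sh2d1a (-1.95) fell and Il1r2 (1.78) rose, with 3 of 13 rising and 7 falling, and the same adjusted over the list alone (adjusted p = 0.075). Among heat shock and stress genes Ier3 (1.72), Atf3 (1.497) and Hspd1 (0.63) rose and Zfp36 (-0.67) fell, with 4 of 11 rising and 2 falling, and the same adjusted over the list alone (adjusted p = 0.181). Of 4 erythroid and platelet markers 0 rose and 0 fell in that limma comparison, with 0 adjusted over the list alone (adjusted p = 0.643), while 7742 genes had an unadjusted p below 0.05.

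Among the lists of markers of other cell types, the myeloid and dendritic one was called lower with activation, and the others were not called. Of 17 myeloid and dendritic cell markers 9 fell and 1 rose, or 9 and 2 adjusted over the list alone, with Lyz2 (-2.26), H2-Aa (-1.25) and Ctss (-1.10) lower and H2-Ab1 (1.66) higher (adjusted p = 0.0105, adjusted p = 0.553 with an estimated correlation). Of 9 B cell markers 5 fell and 1 rose, or 6 and 1 adjusted over the list alone, with Cd79b (-1.11) and Cd79a (-0.89) lower and Ebf1 (2.82) higher (adjusted p = 0.074). Of 11 CD8 and NK markers 3 fell and 1 rose, and the same adjusted over the list alone, with Gzma higher and Xcl1 (-0.68), Klrb1c (-0.62) and Cd8a (-0.55) lower (adjusted p = 0.557).

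Genes that passed with ICOS in fresh cells passed in the same direction in activated cells in 71 cases among the higher genes and 45 among the lower ones, where independent lists would share 15.9 and 24.2. Of the 817 higher genes 47.6% had the same sign in activated cells (median log2 difference -0.029 there), and of the 484 lower ones 53.5% (median -0.027). Without the array that stands apart 218 and 75 were shared, against 27.5 and 22.2, with 57.7% and 60.1% of the same sign. For CD103 the shared counts were 0 and 0, where independent lists would share 0.0562 and 0.0672, so these counts of 0 say little, and 5 and 3 without that array, against 0.141 and 0.0987. The same sign was kept by 57.1% of the 28 higher and 23.1% of the 13 lower genes, and by 58.1% and 56.1% without that array. The fresh and activated arrays are different arrays, but the estimate of the spread is shared.

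Fos and Jun, picked after their values were seen, differed by replicate number in fresh cells. Fos lay between 7.48 and 8.60 on the fresh replicate 1 arrays and between 6.14 and 6.39 on the replicate 2 arrays, and Jun between 10.07 and 11.22 and between 8.44 and 9.59. The median of the immediate early list, relative to each gene's mean over all arrays, lay between 0.22 and 0.47 and between -0.36 and -0.027, but Cd69 lay between 10.76 and 11.15 and between 10.75 and 11.30. Fresh double-negative replicate 1 carried Gzmb at 8.97 and Gzma at 7.91, against 5.21 and 5.16 on replicate 2. Fresh CD103 single-positive replicate 1 carried H2-Aa at 9.23, Ly86 at 7.40 and Ms4a1 at 5.87, against 6.89, 5.68 and 4.53 on replicate 2. Activated double-negative replicate 2 carried Klrd1 at 8.33 and Ifng at 10.16, against 5.19 and 6.83 on replicate 1.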
